A study of Mus musculus with 33 samples.

How the data were processed

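The series profiled mouse ganglionic eminences, the embryonic swellings of the ventral forebrain that give rise to striatal projection neurons and to GABAergic interneurons of the cortex and striatum. Of 33 samples, 8 were RNA-seq libraries of e13.5 tissue (4 wild-type and 4 Dlx1/2 knockout embryos), 9 were ChIP-seq samples of the homeodomain transcription factors DLX1, DLX2 and DLX5 at e11.5, e13.5 and e16.5, 8 were ChIP-seq samples of 4 histone marks in wild-type and knockout tissue at e13.5, and 8 were inputs. Each ChIP condition had 1 library per the labels. The names of the deposited peaks carry a tag that is not explained, so whether a list stands for 1 library or for merged ones was left open. The input files were not used here. Per the labels, the transcription factor ChIP used sonicated chromatin and the histone ChIP used native chromatin cut with micrococcal nuclease, so fragments of the histone libraries follow nucleosomes and depend on the digestion. The labels call the RNA molecule polyA RNA while the library protocol names a kit for ribosome-depleted total RNA. Which of these was used was left open, and it bears on genes without a poly(A) tail.

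The RNA table holds raw read counts per gene symbol, deposited by the authors without normalization. Per the submitters' processing notes the tools were bcl2fastq, STAR 2.4.2a, Trim Galore, BWA 0.7.16a, SAMtools, MACS2 and deepTools, with genome build mm9. The counting tool, the annotation and whether counting used strand are not given in the sources used here, so reads of Dlx1as, Dlx6os1 and Dlx6as2 cannot be told apart with certainty from reads of the genes they overlap on the opposite strand. The same table holds a log2 fold change and a log2 mean expression, a likelihood ratio score and a p-value with its adjusted form, all from the authors' own comparison, per the file headers. Total counts ranged from 14.4 M to 117 M reads, so a change in a low gene is measured most precisely in the deepest library. Of 14664 symbols, 14046 matched a mouse reference table of assembly GRCm38 directly, another 565 matched it through a synonym, and 23 had been turned into dates by a spreadsheet. Only the order of genes along chromosome 2 was taken from that table, for the neighbours of Dlx1 and Dlx2, and no coordinate of it was set beside a peak. Symbols that start with mt-, the prefix of mitochondrial genes, took 0% of the counts in each library. The table may hold no such genes, so this is not a measure of RNA quality. The highest single gene, Rmrp, took at most 1.27%.

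The DLX peak lists give for each peak a fold enrichment over input and the −log10 of its p and q, deposited by the authors, who called peaks per sample with MACS2 per the submitters' processing notes. The histone peak lists hold the same columns, but the deposited −log10 q values reach down to 0.0, so these lists carry no threshold of significance, and results that rest on them are also given for peaks with a −log10 q of at least 5. For each mark the authors also deposited 3 lists of regions from a comparison of the 2 genotypes (higher in condition 1, higher in condition 2, common), with a log10 likelihood ratio as the score of each region, per the file headers. Condition 1 was read as wild type after it was tested on the peak lists: between 82.8% and 97.1% of the regions of condition 1 carried their stronger peak in wild type. Coordinates fit mm9, since the highest coordinate on chromosome 1 was 197194452, as far as that build allows. The read depth of the ChIP libraries is unknown from these files, and the number of peaks called grows with depth, so counts of peaks are not compared between libraries as a measure of binding. No annotation of mm9 was used here, so peaks and regions carry no gene names, and the planned comparison of expression changes with DLX peaks near genes was not run. Alternative chromosomes and random contigs were left out, and DLX intervals listed once per summit were counted once.

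Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr at a minimum count of 10 and Benjamini-Hochberg adjustment at 0.05, knockout against wild type, with 4 embryos per genotype. Fold changes are given as log2 of knockout over wild type, and levels as CPM, the deposited counts scaled to a common library total, as mean ± SD. Tested on simulated data with the real library sizes, the procedure recovered 29.9% of genes changed 1.5-fold, 88.1% of genes changed 2-fold and 100% of genes changed 4-fold, among 14446 genes tested, with 9 false calls. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each two-sided and adjusted over all lists. The 23 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of 465 list genes tested, 41 belong to more than 1 list. The rule names Dlx1, Dlx2, Dlx5 and Dlx6, in each direction the 12 called genes of largest change with a mean of at least 1 CPM and no overlap between the genotypes, and from each list up to 4 members of smallest adjusted p. Some genes that this rule or the screen for values standing apart would name are not reported here. Symbols are those of the deposited table, which uses some older names (Gucy1a3, Epb4.2).

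Replicate numbers are shared by the genotypes. No label says that they pair embryos, but same-numbered libraries deviated together from their group means: the correlations were 0.158, 0.337, 0.483 and 0.566 for replicates 1 to 4, all above the limit of 0.1 fixed for calling the numbers a pairing. Wild-type replicate 1 deviated more like knockout replicate 2 (0.684) than like knockout replicate 1, and wild-type replicate 2 more like knockout replicate 1 (0.485) than like knockout replicate 2. Without sex-linked genes wild-type replicate 1 was still closer to knockout replicate 2 (0.636) than to knockout replicate 1 (0.369), while wild-type replicate 2 was closer to knockout replicate 2 (0.525) than to knockout replicate 1 (0.407). Which libraries within replicates 1 and 2 belong together was left open. The leading principal component (37.0% of the variance) parted replicates 1 and 2 from replicates 3 and 4 in both genotypes and the next one (23.8%) parted the genotypes. No batch is named in the labels. With the genotype in the model, 6487 genes differed between replicates 1 and 2 and replicates 3 and 4. The labels give 2 females and 2 males per genotype, and no sample was grouped by sex. Fits with the replicate number as a block are therefore given beside a gene list where they change its counts. The main fit and the fits without 1 library had no block. No 2 libraries agreed within sampling noise, since the chi-square per degree of freedom between replicates was at least 14.57.

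Peak lists were compared by overlap of at least 1 bp, with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15. Shares carry 95% Wilson intervals that cover counting error only. As background, each list was shifted along its chromosomes at random 100 times (20 times for histone peaks). The overlap procedure, tested on a simulated pair of lists of 3000 intervals with 900 planted overlaps, found 903. Merged DLX regions join peaks of the 3 factors at 1 age. For histone regions that differ, the share holding an e13.5 DLX region was set beside 1000 draws of common regions matched in width. Regions around the chromosome 2 span were set beside draws from the 25 common regions of the same mark nearest in width. Scores and folds of peaks are the authors' own and were used only to rank or filter peaks within a list. With 1 ChIP library per condition no p-value was computed for peaks or regions.

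Alternatives fixed before the data were examined were RLE size factors, library size alone, no filter, a mean of at least 1 CPM, the replicate block, DESeq2 1.42.0, a log2 change of at least 1, leaving out mitochondrial, ribosomal RNA, haemoglobin and sex-linked genes, leaving out each library in turn, stricter peak and region thresholds, overlap of at least 0.5 of the smaller peak, summits within 200 bp and equal numbers of top peaks. Alternatives chosen after seeing the data were replicates 1 and 2 or 3 and 4 as a batch term or on their own, and leaving out the X chromosome or chromosome 2.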

Results

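Expression was measured in ganglionic eminences of 4 wild-type and 4 Dlx1/2 knockout mouse embryos at e13.5, to ask which genes depend on this pair of transcription factors. The wild-type libraries held 117, 20.2, 23.5 and 24.1 M counts and the knockout libraries 42.5, 48.3, 14.4 and 25.8 M. Binding of DLX1, DLX2 and DLX5 was mapped at e11.5, e13.5 and e16.5, and H3K27ac, H3K27me3, H3K4me1 and H3K4me3 were mapped in both genotypes at e13.5, with 1 library per condition. The ChIP comparisons therefore have no replicate check, and their intervals cover counting error only.

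Both targeted genes fell in every knockout library. Dlx1 fell from 124 ± 4.53 CPM in wild type to 23.4 ± 1.97 CPM in knockout (SD, n = 4), to 18.9% of the wild-type level, and Dlx2 fell from 21.2 ± 5.85 to 1.27 ± 0.255 CPM, to 5.79%. On the log2 scale these changes were −2.40 (SE 0.09, edgeR adjusted p = 1.2e-06) and −4.11 (SE 0.24, adjusted p = 9.9e-06). The antisense gene Dlx1as fell further, from 246 ± 23.5 to 0.502 ± 0.398 CPM. Reads of Dlx1 remained at 21.5 to 26.1 CPM in the knockout libraries, and which exons the allele removes is not given in the sources used here. The neighbouring Dlx pair on another chromosome fell as well: Dlx5 from 5.34 ± 0.899 to 0.518 ± 0.173 CPM, Dlx6 from 15.0 ± 1.87 to 2.36 ± 0.284 CPM, and the long noncoding Dlx6os1 from 909.7 ± 164.5 to 25.6 ± 5.04 CPM. All 6 members of the DLX family list that were tested fell (camera adjusted p = 8.3e-205, and adjusted p = 1.4e-06 with an estimated correlation), 6 adjusted over the list alone. This list holds the targeted Dlx1 and Dlx2 and the antisense Dlx1as, so its p-values are in part set by the knockout itself. No list test was run without them.

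Beyond the Dlx genes, the knockout tissue lost transcripts of GABAergic neurons of the striatal and interneuron lineages and gained transcripts of progenitors and of a few genes of other brain regions. Among 14510 genes tested, 85 were higher and 130 lower in knockout, 35 and 71 of them by at least 2-fold. Each of the 215 calls had no overlap between the 4 wild-type and the 4 knockout values. Over all genes tested 868 had none (5.98%), where chance gives 2.86%. With the replicate number as a block, 322 genes were higher and 313 lower, including all 215. DESeq2 called 230 higher and 241 lower, 214 of them among the 215. The count of higher genes dropped to 50 without wild-type replicate 1, 55 without wild-type replicate 2, 54 without wild-type replicate 3, 50 without knockout replicate 1 and 56 without knockout replicate 4. Replicates 1 and 2 differed from replicates 3 and 4 in both genotypes. Replicates 1 and 2 alone gave 178 higher and 202 lower genes and replicates 3 and 4 alone gave 86 and 119. The authors' deposited table lists 147 genes higher and 181 lower at its adjusted p under 0.05, of which 206 were also called here with the same sign.

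**Figure D1:**
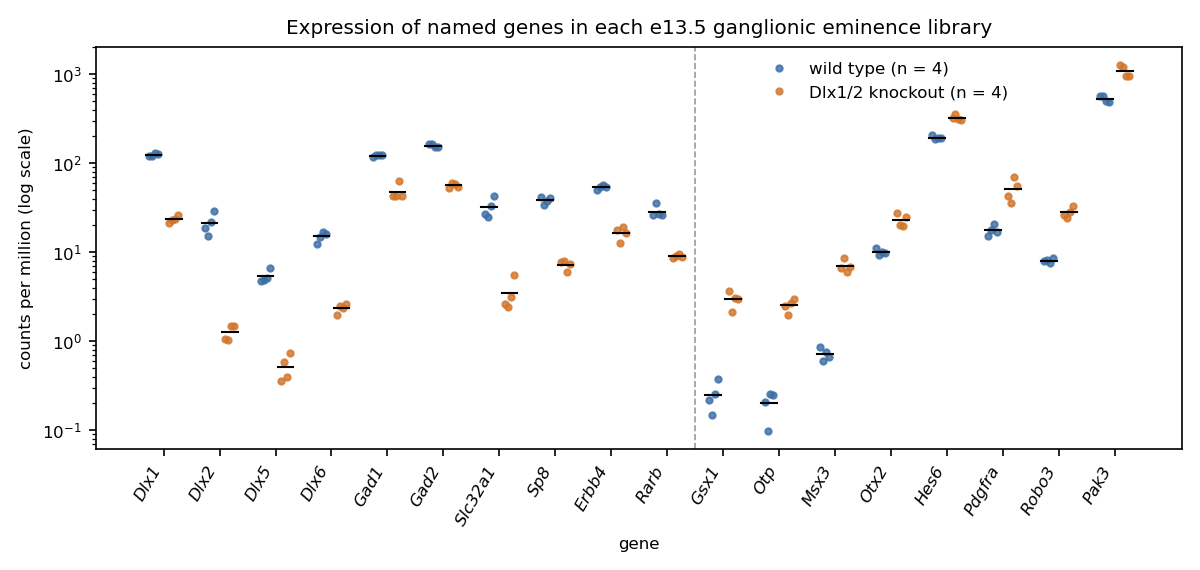
CPM on a log scale for 18 named genes in each of the 8 RNA libraries, with wild type in blue, knockout in orange and black lines at the group means. For each gene the 4 knockout values lie apart from the 4 wild-type values, Dlx1 at 124 against 23.4 and Gsx1 at 0.249 against 2.96 on average.

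Genes that make and package GABA fell. Of 16 tested genes of GABA synthesis, release and uptake, 3 fell, and 3 did so adjusted over the list alone: Slc32a1, the vesicular GABA transporter, from 31.9 ± 8.04 to 3.44 ± 1.43 CPM (log2 −3.23, SE 0.28, adjusted p = 0.0002), and the glutamate decarboxylase genes Gad2 (−1.49, SE 0.08, adjusted p = 7.7e-06) and Gad1 (−1.35, SE 0.13, adjusted p = 0.00045). The remaining members, mostly subunits of GABA receptors and GABA transporters, did not pass the test. Abat, the GABA transaminase, had a log2 change of −0.59 (SE 0.22, adjusted p = 0.43), and with the replicate block it passed (adjusted p = 0.00095). As a list these genes were lower (camera adjusted p = 5.0e-12, and adjusted p = 0.0195 with an estimated correlation).

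Transcription factors of the GABAergic lineage fell as a group. Of 31 tested, 12 fell and 1 rose, and 17 fell and 4 rose adjusted over the list alone. Sp8, a zinc finger factor of the lateral and caudal eminences, fell from 38.6 ± 3.57 to 7.28 ± 0.861 CPM (log2 −2.40, SE 0.12). The member that rose was Prox1 (0.84, SE 0.15, adjusted p = 0.0234), named after its value was seen. The list was lower with camera (adjusted p = 1.1e-36, and adjusted p = 0.0032 with an estimated correlation). With the replicate block the counts were 17 lower and 4 higher, with Peg10 and Meis2, chosen after their values were seen, among the genes gained.

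Genes of striatal projection neurons, the main output neurons of the later striatum, fell in the knockout. Of 28 tested, 10 fell and 0 rose, or 15 and 1 adjusted over the list alone (camera adjusted p = 2.3e-46, and adjusted p = 0.00019 with an estimated correlation). The retinoid receptor genes Rxrg and Rarb fell 5.07-fold and 3.17-fold, and Gucy1a3, a subunit of guanylate cyclase, fell 3.78-fold. The replicate block gave 16 lower and 1 higher.

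Interneuron genes fell as a group, with exceptions. Of 27 tested markers of cortical and striatal interneurons, 11 fell and 2 rose, or 16 and 2 adjusted over the list alone (camera adjusted p = 1.3e-43, and adjusted p = 0.00019 with an estimated correlation). Nxph2, a neurexophilin, fell 22.0-fold, from 12.7 ± 2.86 to 0.578 ± 0.188 CPM. Crabp1, a retinoic acid binding protein, fell 7.29-fold, and Erbb4, the neuregulin receptor of migrating interneurons, 3.28-fold. The members that rose were Npy (log2 0.99, SE 0.10, adjusted p = 0.00079) and Prox1, both named after their values were seen. With the replicate block 16 fell and 2 rose. Markers of the medial eminence and cholinergic neurons went in both directions: of 20 tested, Lhx8 (−1.31, SE 0.16) and Lhx6 (−0.85, SE 0.14) fell and Sall3 (0.81, SE 0.11) rose, and 3 fell and 4 rose adjusted over the list alone. The replicate block also gave 3 and 4, though not all of them the same genes. Nkx2-1, which sets medial identity and was chosen after its values were seen, had 19.9 ± 2.29 CPM in wild type and 23.4 ± 4.64 CPM in knockout. That list did not differ from other genes (camera adjusted p = 0.53). Lhx6 lost its call without wild-type replicate 3 (adjusted p = 0.0514) or knockout replicate 1 (adjusted p = 0.0543).

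Progenitor genes of the ventricular zone rose. Of 40 tested, 5 rose and 0 fell, or 17 and 0 adjusted over the list alone, and the list was higher (camera adjusted p = 3.5e-20, and adjusted p = 0.0383 with an estimated correlation). Gsx1, a homeodomain factor of eminence progenitors, rose from 0.249 ± 0.0948 to 2.96 ± 0.644 CPM (log2 3.59, SE 0.28). Otx2 rose by 1.20 (SE 0.13), Ednrb by 0.82 (SE 0.10), Hes6 by 0.74 (SE 0.08) and Jag1 by 0.50 (SE 0.10) on the log2 scale. With the replicate block 21 members rose, among them, chosen after their values were seen, Gsx2, Hes5, Sox9 and Lhx2. Of 24 genes of the Notch pathway, which keeps progenitors undifferentiated, 3 rose, namely Hes6, Jag1 and Mfng (0.47, SE 0.09), and 8 rose adjusted over the list alone. The Notch list was higher with camera (adjusted p = 6.2e-09) but not when its correlation was estimated (adjusted p = 0.115 with an estimated correlation), and 11 members rose with the replicate block. Mfng lost its call without any 1 of 7 libraries (adjusted p from 0.0717 to 0.132, kept without knockout replicate 3), and Jag1 likewise (0.0596 to 0.13, kept without knockout replicate 1). None of 40 cell cycle genes was called by edgeR or adjusted over the list alone. Mki67 was at 354 ± 17.2 CPM in wild type and 389 ± 38.1 CPM in knockout (log2 0.14, SE 0.09).

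**Figure D2:**
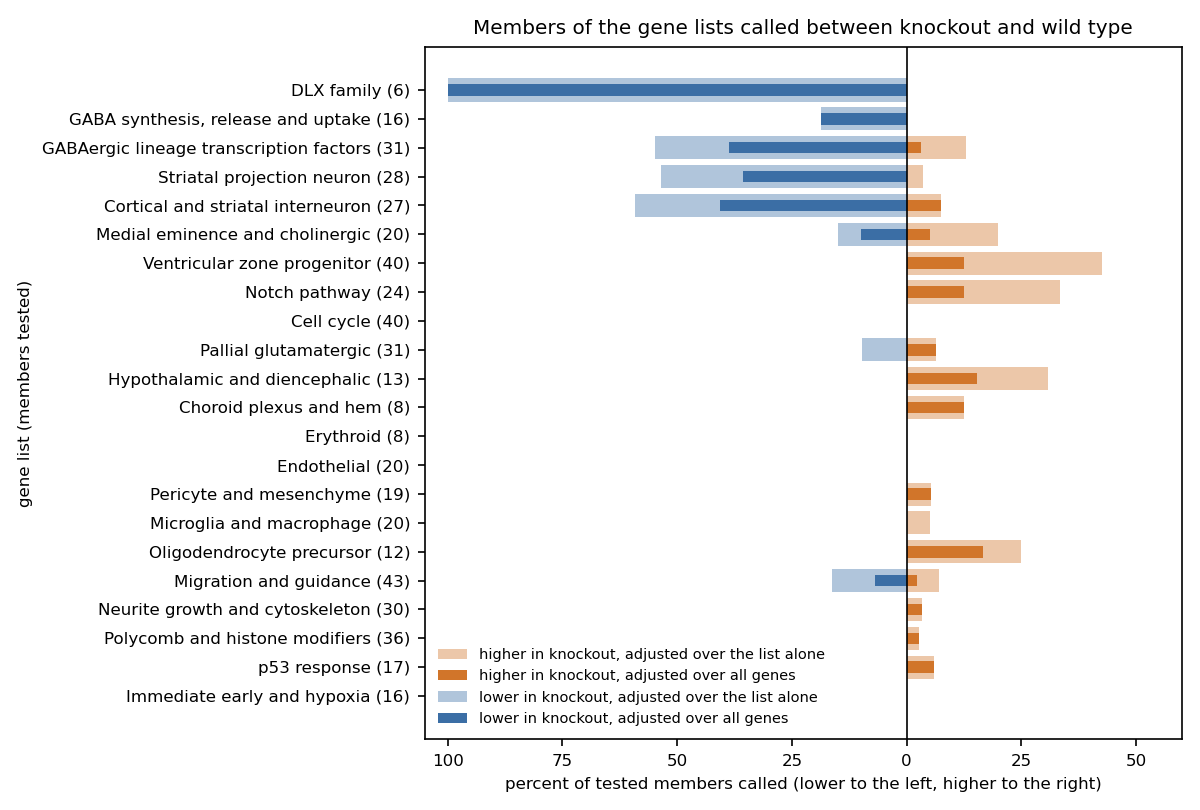
Percent of tested members of each gene list called higher (right, orange) or lower (left, blue) in knockout, with dark bars adjusted over all genes and pale bars adjusted over the list alone. GABAergic, striatal and interneuron lists lie to the left, and the progenitor list has 5 of 40 members to the right, or 17 adjusted over the list alone.

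Several genes of other brain regions, low in wild type, rose in the knockout eminences. Otp, a hypothalamic homeodomain gene, rose from 0.203 ± 0.0725 to 2.53 ± 0.426 CPM (log2 3.57, SE 0.26). Msx3, a gene of the dorsal neural tube, rose 9.46-fold from 0.720 ± 0.115 to 7.06 ± 1.16 CPM, and Tal2, a midbrain factor, 4.30-fold. Of 13 hypothalamic and diencephalic markers tested, Otp and Hmx2 (2.72, SE 0.53) rose, and 4 rose adjusted over the list alone (camera adjusted p = 4.4e-10, and adjusted p = 0.0027 with an estimated correlation), with 3 under the replicate block. Only 14 of the 31 members of this list were in the deposited table. Otp had 38 wild-type and 317 knockout reads and Hmx2 had 31 and 148, so a member can enter the test mainly through its knockout reads. The list test therefore does not speak for all members. Hmx2 lost its call without any 1 of 6 libraries (adjusted p from 0.0774 to 0.171, kept without wild-type replicate 4 or knockout replicate 2). Of 39 HOX and posterior patterning genes only Pax7 and Pax5 were in the table used here, and both were tested and rose, also adjusted over the list alone. Pax7 had 3 reads in the 4 wild-type libraries and 141 in the 4 knockout libraries, a ratio of 65.4 per count sequenced (counting interval 21.9 to 321), and Pax5 had 12 and 94, a ratio of 10.9 (5.95 to 21.8). Both can enter the table mainly through their knockout reads, so their rise does not speak for the other members of that list.

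Markers of cortical glutamatergic cells did not move as a group. Of 31 tested, Lhx9 (log2 0.63, SE 0.09) and Ebf3 (1.01, SE 0.18) rose, while 2 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.7), and 2 rose and 2 fell with the replicate block. Its median change was 0.03 and its mean −0.05, so their signs differ. Ebf3 lost its call without any 1 of 5 libraries (adjusted p from 0.05 to 0.074, kept without wild-type replicate 4 or knockout replicates 2 or 3). Of 8 choroid plexus and hem genes Otx2 alone rose, also adjusted over the list alone. That list had camera adjusted p = 0.0344, and adjusted p = 0.115 with an estimated correlation, and lost its call without wild-type replicate 1 (0.178), wild-type replicate 3 (0.187), knockout replicate 1 (0.0807) or knockout replicate 4 (0.141).

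Early glial genes were higher in part. Pdgfra, the receptor that marks oligodendrocyte precursors and mesenchyme, rose from 17.7 ± 2.46 to 51.0 ± 15.0 CPM (log2 1.53, SE 0.20) and Gpr17 from 1.61 ± 0.0945 to 3.51 ± 0.742 CPM. These were the 2 of 12 tested precursor genes that rose, with 3 adjusted over the list alone (camera adjusted p = 1.7e-05, but adjusted p = 0.163 with an estimated correlation). With the replicate block 4 rose. Gpr17 lost its call without any 1 of 5 libraries (adjusted p from 0.0623 to 0.0717, kept without wild-type replicate 4 or knockout replicates 2 or 3). Among 19 pericyte and mesenchyme genes Pdgfra alone rose, also adjusted over the list alone (camera adjusted p = 0.0344, and adjusted p = 0.115 with an estimated correlation). That call ended without wild-type replicate 2 (0.104) or knockout replicate 4 (0.0923), and 2 genes rose with the replicate block. None of 20 microglia and macrophage genes was called by edgeR, and 1 rose adjusted over the list alone (camera adjusted p = 0.0104, but adjusted p = 0.163 with an estimated correlation), with 2 under the replicate block.

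Blood and vessel markers gave no called gene by edgeR, adjusted over all genes or adjusted over the list alone. Of 8 erythroid genes Hbb-y, an embryonic globin chosen after its values were seen, was at 1782 ± 103 CPM in wild type and 1726 ± 271 CPM in knockout (list camera adjusted p = 0.0823). The list as a whole leaned higher in knockout, with a median log2 change of 0.592 and a mean of 0.585. Epb4.2 was at 0.986 ± 0.472 CPM in wild type and 2.11 ± 2.37 CPM in knockout, with 5.645 CPM in knockout replicate 2. Equal blood content is therefore not shown. Without knockout replicate 1 the erythroid list was higher (adjusted p = 0.00139). Of 20 endothelial genes Cldn5 was at 30.6 ± 8.57 CPM in wild type and 25.9 ± 4.49 CPM in knockout (list camera adjusted p = 0.53).

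Guidance receptors changed in both directions. Of 43 migration and guidance genes, Robo3 rose 3.47-fold, from 8.08 ± 0.412 to 28.03 ± 3.93 CPM, while Erbb4, Robo2 (log2 −0.51, SE 0.07) and Ackr3 (−0.76, SE 0.12), a chemokine receptor of migrating interneurons, fell. Adjusted over the list alone 3 rose and 7 fell, and with the replicate block 6 rose and 7 fell. The list did not lean one way (camera adjusted p = 0.696), and fry found members changing in either direction (mixed adjusted p = 6.1e-08). Its median change was 0.02 and its mean −0.01. Of 30 neurite and cytoskeleton genes Pak3, a p21-activated kinase, rose from 532 ± 46.1 to 1092 ± 158 CPM, and 1 rose adjusted over the list alone (camera adjusted p = 0.916). Stmn2 fell as well with the replicate block. Of 36 Polycomb and histone modifier genes Hdac9 rose (0.57, SE 0.11), also adjusted over the list alone (camera adjusted p = 0.875, median change −0.02 and mean 0.00). Hdac9 lost its call without any 1 of 7 libraries (adjusted p from 0.0558 to 0.109, kept without wild-type replicate 1). Of 17 p53 response genes Cdkn1a, a cell cycle inhibitor, rose (1.07, SE 0.16), also adjusted over the list alone (camera adjusted p = 0.0823). Plk2 fell as well with the replicate block. The p53 list was higher without wild-type replicate 4 (0.0477). None of 16 immediate early and hypoxia genes was called by edgeR or adjusted over the list alone (camera adjusted p = 0.53). Fos was at 0.541 ± 0.132 CPM in wild type and 0.343 ± 0.124 CPM in knockout.

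Several genes of large change belong to no list. Aldh1a3, an enzyme that makes retinoic acid, fell 11.8-fold from 14.4 ± 1.95 to 1.21 ± 0.419 CPM. Cntnap3, a contactin-associated protein, fell from 15.9 to 1.72 CPM and Neb, which encodes nebulin, from 15.6 to 2.13 CPM. The predicted gene Gm14204 fell 13.7-fold, from 113 ± 17.7 to 8.18 ± 3.04 CPM, and Dlx6as2 fell 22.4-fold. Among genes that rose, Npnt, an extracellular matrix protein, rose 2.58-fold. Fam101a, Tacr1, Lingo4 and Acss3, each named by the rule, rose between 2.55-fold and 2.80-fold, and each lost its call without wild-type replicate 1 (adjusted p = 0.0629, 0.0994, 0.0659 and 0.0902 in that order). Tacr1 lost it without any 1 of 6 libraries (0.0508 to 0.0994, kept without wild-type replicate 4 or knockout replicate 4), Acss3 without any 1 of 5 (0.0651 to 0.0902, kept without wild-type replicate 2 or knockout replicates 2 or 3) and Lingo4 also without wild-type replicate 3 (0.0547) or knockout replicate 1 (0.0654). BC049730 had 27 reads in the wild-type libraries, all in replicate 3, and 1227 in the knockout libraries (ratio 63.2, counting interval 43.2 to 96.3). Its call (adjusted p = 0.0351) was lost with DESeq2 (adjusted p = 0.36) and without any 1 of 6 libraries (adjusted p from 0.067 to 0.107, kept without wild-type replicate 3 or knockout replicate 3).

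The 3 DLX factors were mapped by ChIP-seq in wild-type eminences at 3 ages to ask where they bind and how far they share sites. DLX1 had 4337 peaks at e11.5, 8459 at e13.5 and 16817 at e16.5. DLX2 had 8341, 17126 and 32610, and DLX5 had 11361, 2951 and 27370. Peaks were narrow, with median widths from 267 bp to 331 bp, and covered between 1.03 Mb and 12.8 Mb of the genome. Median fold enrichment over input ranged from 4.31 to 5.96. The depth of these libraries is unknown, so the low count of DLX5 at e13.5 cannot be read as fewer sites.

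The strongest peaks recurred. The peak of highest −log10 q at chr17:39979800-39985915 (mm9) for DLX2 at e11.5 had a fold enrichment of 87.0, lay under peaks of all 9 DLX lists and overlapped wild-type peaks of all 4 histone marks with a −log10 q of at least 5. A peak at chr9:35112652-35113240, with a fold of 54.5 in the same list, was likewise in all 9 lists and under all 4 marks. The chr17 peak was 6116 bp wide, where the median width of its list was 306 bp. Peaks were not filtered for places of high signal in every library, so whether these 2 recurrent peaks are DLX binding was not tested. DLX1 had its top e13.5 peaks elsewhere, at chr9:119231403-119232142 (fold 72.6) and chr17:27340984-27342126 (fold 72.0), each found in 7 of the 9 lists. At e16.5 its list added chr2:164704039-164705672 (fold 62.5, in 6 lists). The DLX2 list at e16.5 had chr5:132345402-132346413 (fold 56.7) among its 2 strongest, a site in all 9 lists that overlapped H3K4me1 but none of the other 3 marks.

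DLX peaks overlapped between factors far more often than lists placed at random, while most merged regions at e11.5 and e13.5 held 1 factor. At e13.5, 88.2% of DLX5 peaks (87.0 to 89.3) overlapped a DLX2 peak and 77.9% (76.3 to 79.3) a DLX1 peak, where lists placed at random gave 0.508% and 0.203%. Of DLX1 peaks, 67.3% (66.3 to 68.3) overlapped DLX2. The median over the 3 factor pairs, shorter list in longer, was 57.8% at e11.5, 77.9% at e13.5 and 77.9% at e16.5, and for DLX2 in DLX5 at e11.5 the share was 49.4%. The samples hold 1 input for the 3 factors at e11.5 and 1 at e16.5, and random placement does not allow for overlap that a shared input brings, whereas at e13.5 each factor has its own. These shares depend on how many peaks were called: with the 2951 strongest peaks of each list the medians were 42.0%, 48.0% and 59.6%. Merged over the factors there were 16127 regions at e11.5, 20054 at e13.5 and 42503 at e16.5. Regions of 1 factor made up 66.2%, 70.1% and 50.4% of them and regions of all 3 factors 12.5%, 10.4% and 27.3%. Of the 100 strongest DLX2 peaks at e13.5, 100 also lay in the DLX1 list and 100 in the DLX5 list of that age. Of the 100 strongest DLX1 peaks, 73 lay in the DLX2 list and 78 in the DLX5 list, and of the 100 strongest DLX5 peaks, 97 lay in the DLX1 list and 95 in the DLX2 list.

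Sites persisted across ages. For DLX2, 86.2% of e11.5 peaks (85.4 to 86.9) lay under an e13.5 peak and 90.4% under an e16.5 peak. For DLX1 the medians over pairs of ages came to 70.0%, and for DLX5 to 68.2%, against 0.339% to 0.528% at random in the 3 factors. Of the DLX5 peaks at e13.5, 94.9% lay under an e16.5 peak. Of 4337 DLX1 peaks at e11.5, 1044 overlapped peaks in all 9 lists. With the 2951 strongest peaks of each list, the medians were 44.0% for DLX1, 71.5% for DLX2 and 42.6% for DLX5.

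At e13.5 DLX regions lay in chromatin marked by H3K4me1 and H3K4me3 more often than by H3K27me3. Of the 20054 regions, 58.1% (57.4 to 58.8) overlapped a wild-type H3K4me1 peak with a −log10 q of at least 5, 42.5% (41.9 to 43.2) an H3K4me3 peak, 25.5% (24.9 to 26.1) an H3K27ac peak and 17.7% (17.2 to 18.2) an H3K27me3 peak. Regions placed at random gave 7.33%, 3.66%, 2.01% and 2.61%. Regions of all 3 factors carried H3K4me1 in 69.3% (67.3 to 71.3), against 56.2% (55.4 to 57.0) of regions of 1 factor, while for H3K27ac the order was the other way, 21.6% (19.9 to 23.4) against 26.2% (25.5 to 26.9). Over the whole deposited histone lists the shares were 81.3%, 79.3%, 79.1% and 39.7%, against 19.1%, 7.47%, 27.1% and 15.7% at random, and there regions of all 3 factors overlapped H3K27ac more often than regions of 1 factor (87.9% against 77.6%). By combination of strict peaks, 26.8% of regions had H3K4me3 without H3K27me3, 24.97% had H3K4me1 alone, 15.7% had H3K4me3 together with H3K27me3, and 29.4% had none of the 4 marks.

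**Figure D3:**
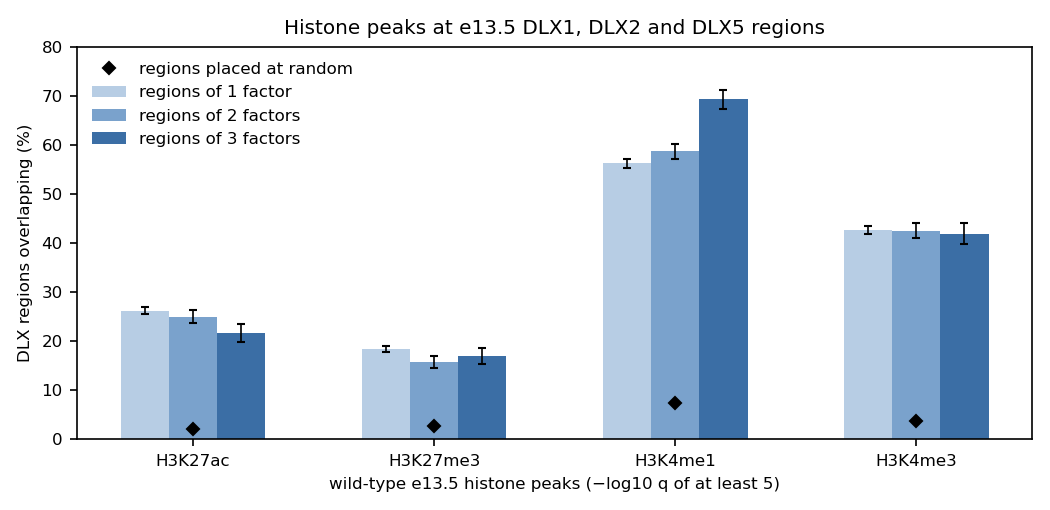
Percent of e13.5 DLX regions that overlap wild-type histone peaks with a −log10 q of at least 5, by the number of DLX factors at the region, with 95% Wilson intervals (counting error only) and black diamonds for regions placed at random. H3K4me1 is highest at regions of 3 factors, 69.3% against 56.2% for 1 factor.

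Histone profiles of the genotypes were compared to ask where chromatin differs when Dlx1 and Dlx2 are missing. The authors' lists hold 700 H3K27ac regions higher in wild type and 546 higher in knockout, beside 37842 common ones. For H3K4me1 the numbers were 2936 and 1906, and for H3K4me3 360 and 1686. For H3K27me3 5116 regions were higher in wild type and 662 higher in knockout, but 4671 of the 5116 (91.3%) lay on the X chromosome, and without the X there were 445 and 661. H3K27me3 peaks with a −log10 q of at least 5 on the X numbered 69 in wild type and 73 in knockout, against 14157 and 2594 in the whole lists. With a likelihood ratio of at least 5 the order for H3K4me3 stayed the same (206 and 291), as it did for H3K27ac (270 and 155).

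The largest difference in 3 marks fell on 1 place. On chromosome 2, H3K4me3 (chr2:71368511-71384091, log10 likelihood ratio 262), H3K27ac (chr2:71368480-71384309, 187) and H3K4me1 (chr2:71373965-71381374, 117) were each higher in wild type there, and H3K27me3 (chr2:71364449-71384488, 180) had its next to largest difference there. Over the 15581 bp from the start to the end of the places higher in wild type in all 4 marks, wild-type peaks covered 100% in each mark and knockout peaks covered 1.44% for H3K27ac, 0.340% for H3K27me3, 0% for H3K4me1 and 2.12% for H3K4me3. With peaks of a −log10 q of at least 5 wild type stayed at 100% in each mark and knockout at 0.616%, 0.340%, 0% and 2.12%. At e13.5 this span held 3 DLX1, 11 DLX2 and 3 DLX5 peaks. Dlx1 and Dlx2 lie on chromosome 2, and whether the span holds them was not determined, since no annotation of mm9 was used here. No other place was higher in wild type in all 4 marks. A site of 526 bp at chr4:119032031-119032556 was higher in knockout in all 4.

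**Figure D4:**
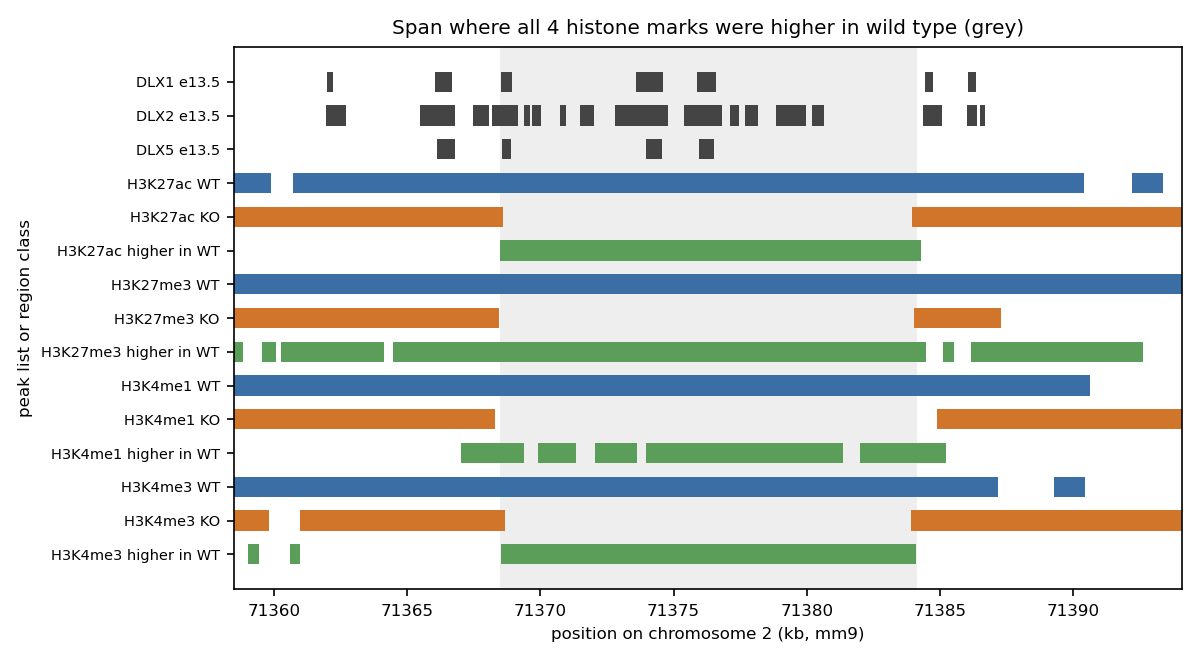
Map of the chromosome 2 span (mm9, kb on the horizontal axis, 10 kb added on each side) with e13.5 DLX peaks in dark grey, wild-type histone peaks in blue, knockout histone peaks in orange and regions higher in wild type in green. The shaded span of 15581 bp is covered by wild-type peaks of all 4 marks and nearly empty of knockout peaks, at most 2.12% in H3K4me3.

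Other leading regions differed in 1 or 2 marks. On the X chromosome H3K4me3 was higher in wild type at chrX:100675444-100679372 (likelihood ratio 83.7), with H3K27ac higher inside it at chrX:100677194-100677858 (20.3). At chrX:103398727-103399707 H3K4me3 was higher in knockout (155), again with H3K27ac (chrX:103398904-103399456, 26.0). H3K4me3 was also higher in knockout at chr13:115721313-115722694 (156) and H3K27ac at chr13:95644842-95648262 (19.8). H3K27me3 was higher in wild type at chr2:93488332-93490054 (197) and higher in knockout at chr17:36360126-36362993 (84.6) and chr13:72474119-72477414 (48.1). H3K4me1 was higher in wild type at chr17:13674028-13675125 (83.3) and higher in knockout at chr2:104512473-104513138 (115) and chr2:57037373-57037886 (70.1). Of these, only chr13:95644842-95648262 overlapped a DLX region, of 1 factor.

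Regions that lost an active mark in the knockout were enriched for DLX binding. Of the 700 H3K27ac regions higher in wild type, 29.9% (26.6 to 33.3) held an e13.5 DLX region, against a median of 11.3% (95% range 9.43 to 13.4) in draws of common regions of the same widths. For H3K4me1 the share was 23.2% (21.7 to 24.7) against 4.09% (3.41 to 4.77), and for H3K4me3 49.2% (44.0 to 54.3) against 17.5% (14.2 to 21.7). None of 1000 draws reached these shares. Regions higher in knockout showed no such excess: 8.97% for H3K27ac against 9.52% drawn, 1.52% for H3K4me1 against 2.99%, and 13.46% for H3K4me3 against 16.96%. H3K27me3 regions higher in knockout held DLX in 7.40% (5.64 to 9.65) against 7.86% drawn. With DLX peaks of a −log10 q of at least 5 their share was 6.50% (4.86 to 8.64) against 4.68% drawn (3.17 to 6.34), and 15 of 1000 draws were as high. With at least 2 factors it was 3.32% against 2.42% drawn (1.36 to 3.63), and 72 of 1000 draws were as high. Whether these H3K27me3 regions hold more DLX therefore depends on the DLX peaks used. H3K27me3 regions higher in wild type held DLX in 1.35% against 9.60%, and without the X chromosome in 7.42% (5.33 to 10.2) against 8.99%. Of the 209 occupied H3K27ac regions, DLX2 peaks lay in 208, DLX1 peaks in 112 and DLX5 peaks in 66.

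**Figure D5:**
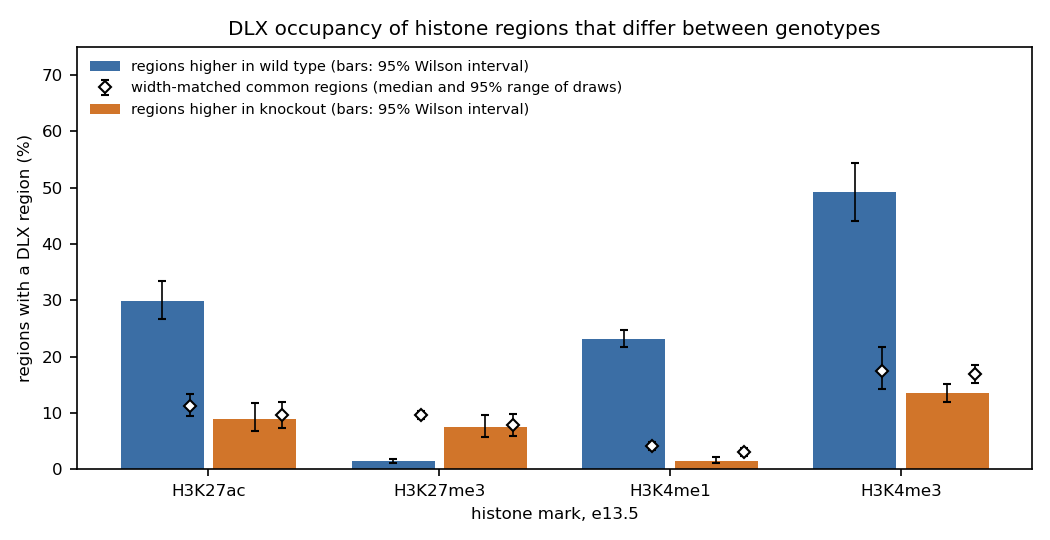
Percent of regions that differ between genotypes and hold an e13.5 DLX region, by histone mark, for regions higher in wild type (blue) and in knockout (orange), with 95% Wilson intervals (counting error only) and white diamonds for the median and 95% range of width-matched common regions. Wild-type H3K27ac, H3K4me1 and H3K4me3 regions stand above their draws, at 29.9%, 23.2% and 49.2%.

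Where H3K27ac changed together with H3K4me1 or H3K4me3, the marks mostly changed in the same direction, but many H3K27ac regions that changed overlapped regions of the other mark common to the genotypes. Of the 700 H3K27ac regions higher in wild type, 189 (27.0%, 23.8 to 30.4) overlapped H3K4me1 regions higher in wild type 5 overlapped H3K4me1 regions higher in knockout and 490 overlapped common ones. With H3K4me3 the counts were 78, 2 and 199. Of the 546 H3K27ac regions higher in knockout, 45 (8.24%) overlapped H3K4me1 regions higher in knockout, 1 overlapped a region higher in wild type and 440 overlapped common ones. H3K27me3 went the other way at a few places: of 662 regions where it was higher in knockout, 24 (3.63%, 2.45 to 5.34) overlapped H3K27ac regions higher in wild type and 3 (0.453%) overlapped H3K27ac regions higher in knockout. Counted over the 700 H3K27ac regions higher in wild type, the lean was weaker. Of these, 12 (1.71%, 0.983 to 2.97) overlapped H3K27me3 higher in knockout and 6 (0.857%, 0.393 to 1.86) H3K27me3 higher in wild type, with overlapping intervals. The 24 H3K27me3 regions above lay on these 12 H3K27ac regions. Neighbours at 1 place were thus counted separately, which their interval does not allow for.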

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

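The values of each group of 4 libraries were screened with Dixon's ratio for 1 value standing apart. Of 198 groups looked at, 14 lay beyond the critical value. Chance flags about 1 in 20 groups, so some of these are due to chance, and none was left out of any fit.

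The total count of wild-type replicate 1 was 117 M reads, above the other 3 wild-type libraries at 20.2 to 24.1 M. In wild type, Rarb stood at 35.82 CPM in replicate 2, Mki67 at 328.5 CPM in replicate 1, Pax7 at 0.02625 CPM in replicate 1 and BC049730 at 1.146 CPM in replicate 3. Pax7 and BC049730 had no reads in the other 3 wild-type libraries.

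In knockout, replicate 1 stood apart for Npnt (9.534 CPM) and Sall3 (38.73 CPM), and replicate 3 for Gad1 (62.79 CPM) and Foxd1 (1.471 CPM). Replicate 2 stood apart for Gm14204 (12.69 CPM), Gpr17 (2.404 CPM) and the erythroid gene Epb4.2 (5.645 CPM).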

How the results depend on the processing

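Values here were recomputed with 1 choice changed at a time, and where a result moved the cause was not tested. The batch term, replicates 1 and 2 or 3 and 4 on their own, and leaving out the X chromosome or chromosome 2 were chosen after seeing the data. The planned comparison of genes near DLX peaks was not run for want of an annotation of mm9.

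The RNA counts of 85 higher and 130 lower genes became 322 and 313 with the replicate block, 230 and 241 with DESeq2, 35 and 71 with a log2 change of at least 1, 333 and 336 with the batch term, and 178 and 202 with replicates 1 and 2 alone. Replicates 3 and 4 alone gave 86 and 119. Without 1 library, higher genes ranged from 50 to 66 and lower genes from 92 to 121. Higher genes moved without wild-type replicates 1 (50), 2 (55) and 3 (54) and knockout replicates 1 (50) and 4 (56). The replicate block kept all 215 calls and brought the total to 635, with the counts of list members given beside the lists. No test of a whole list changed its call with the block.

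Of 54 named genes called, BC049730 alone lost its call with all 8 libraries (DESeq2, 0.359), 12 lost it when any library was left out, and 0 reversed.

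Among gene lists, choroid plexus lost its call with no filter on low counts (0.0606), the batch term (0.0681), replicates 1 and 2 alone (0.313) and an estimated correlation (0.115). Without 1 library its adjusted p ranged from 0.0138 to 0.187, with the call lost without wild-type replicates 1 (0.178) and 3 (0.187) and knockout replicates 1 (0.0807) and 4 (0.141). Pericyte lost its call with library size only (0.0518), at least 1 CPM (0.146) and an estimated correlation (0.115), and ranged from 0.0166 to 0.104, lost without wild-type replicate 2 (0.104) and knockout replicate 4 (0.0923). Microglia lost it with replicates 3 and 4 alone (0.205), an estimated correlation (0.163) and fry (0.0663). Oligodendrocyte precursor lost it with an estimated correlation (0.163) and fry (0.0774), and Notch with an estimated correlation (0.115). The p53 list gained a call with fry (0.0362), with replicates 1 and 2 alone (0.038) and without wild-type replicate 4 (0.0477, range 0.0477 to 0.166). Erythroid gained one without knockout replicate 1 (0.00139, range 0.00139 to 0.775) and without mitochondrial, ribosomal RNA, haemoglobin and sex-linked genes (0.0448).

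For the other lists no call changed without 1 library, and the adjusted p ranged as follows: DLX family 1.64e-237 to 6.66e-181, GABA synthesis 8.11e-15 to 7.54e-10, GABAergic factors 1.04e-38 to 7.9e-27, striatal 2.94e-47 to 7.64e-39, interneuron 5.94e-44 to 2.88e-35, medial 0.135 to 0.981, progenitor 1.47e-25 to 2.02e-15, Notch 8.52e-12 to 2.93e-06, cell cycle 0.173 to 0.944, pallial 0.104 to 0.972, hypothalamic 2.25e-11 to 2.56e-08, endothelial 0.0923 to 0.962, microglia 0.00106 to 0.0432, oligodendrocyte precursor 1.95e-09 to 0.000694, migration 0.309 to 0.981, neurite 0.33 to 0.929, Polycomb 0.739 to 0.994 and immediate early 0.273 to 0.949.

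DLX peaks at a −log10 q of at least 5 moved to 2108 (DLX1 e11.5), 5356 (DLX2 e11.5), 4371 (DLX5 e11.5) and 1502 (DLX5 e13.5). At a fold of at least 5 they moved to 1449, 4998 and 5863 for DLX1 at e11.5, e13.5 and e16.5, 3812 and 15390 for DLX2 at e11.5 and e16.5, and 4371, 1502 and 8849 for DLX5 at e11.5, e13.5 and e16.5.

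Median overlap between factors at e11.5, e13.5 and e16.5 was 55.98, 76.01 and 75.51% where the overlap had to reach 0.5 of the smaller peak, 52.25, 70.52 and 71.52% for summits within 200 bp, and 42.05, 47.98 and 59.61% for the same number of top peaks. Between ages it was 84.69% (DLX2) and 65.84% (DLX5) by share of the smaller peak. For DLX1, DLX2 and DLX5 it was 66.2, 80.05 and 60.18% by summits and 44.02, 71.54 and 42.56% by top peaks.

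DLX regions with H3K27ac, H3K27me3, H3K4me1 and H3K4me3 were 25.47, 17.68, 58.08 and 42.54% at a histone −log10 q of at least 5, and 76.43, 34.81, 78.36 and 76.97% with the DLX summit inside the histone peak.

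Differing regions at a likelihood ratio of at least 5 were 270 and 155 for H3K27ac (higher in wild type and in knockout), 1625 and 471 for H3K4me1, 206 and 291 for H3K4me3, and 213 for H3K27me3 higher in knockout. Without the X chromosome H3K27me3 higher in wild type fell to 445.

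DLX occupancy with at least 2 factors was 20.43 and 2.93% for H3K27ac higher in wild type and in knockout, 0.7232 and 3.323% for H3K27me3, 11.0 and 0.4197% for H3K4me1, and 35.28 and 3.855% for H3K4me3. At a likelihood ratio of at least 5 it was 38.52% for H3K27ac and 28.06% for H3K4me1 higher in wild type, and 10.33% for H3K27me3 and 8.935% for H3K4me3 higher in knockout. With DLX peaks of a −log10 q of at least 5 it was 6.777% (H3K27ac), 1.049% (H3K4me1) and 8.719% (H3K4me3) higher in knockout, and 20.88% for H3K4me1 higher in wild type. H3K27me3 higher in wild type held 7.416% without the X chromosome and 0.9163% without chromosome 2.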

Other observations

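The places and patterns of this part, and all of its tests, were chosen after the result was seen. DLX peaks crowded on 1 stretch of 200 kb on chromosome 2, chr2:77700001-77900000 (mm9). The 1 Mb window around it held the most peaks in 8 of the 9 DLX lists, and the stretch held 4.13% of the DLX5 peaks at e13.5 (122 of 2951) and 0.160% to 0.853% of the peaks of the other 8 lists. Peaks with a −log10 q of at least 5 covered 16.1% of it in the DLX5 list at e13.5 and 49.7% to 60.7% in the other 8. Wild-type histone peaks covered 61.75% of it for H3K27ac, 35.06% for H3K27me3, 25.26% for H3K4me1 and 31.59% for H3K4me3, and knockout peaks covered 9.70%, 13.67%, 8.25% and 4.31%. Regions higher in wild type numbered 18, 16, 11 and 1 for these marks, and none was higher in knockout. With peaks of a −log10 q of at least 5 the marks covered 3.94%, 5.05%, 12.4% and 3.27% in wild type and 0.786%, 0%, 1.44% and 2.33% in knockout. Peaks were not filtered for places of high signal in every library, and the inputs were not used. Whether this crowding is DLX binding was therefore not tested, nor whether the difference in the marks depends on such binding.

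A stretch of chromosome 6, chr6:6787170-6856797, lies in the autosomal 1 Mb window with the most H3K27me3 regions higher in knockout. It held 21 of these and none higher in wild type. Another 18 H3K27me3 regions there were common to the genotypes. In the same stretch 3 H3K27ac and 4 H3K4me3 regions were higher in wild type, H3K4me1 went both ways (6 higher in wild type and 3 in knockout), and 5 DLX1, 14 DLX2 and 3 DLX5 peaks of e13.5 lay there. On chromosome 2, 4 of 48 genes tested within 25 genes of Dlx1 and Dlx2 were called (8.33%, against 1.44% elsewhere, Fisher exact p = 0.00522): Fastkd1 (log2 1.21) and Metap1d (1.16) rose and Gad1 (−1.35) and Cdca7 (−0.53) fell. Within 10, 50 and 100 genes the shares were 11.1%, 5.1% and 3.54%, with Fisher exact p = 0.0279, 0.0144 and 0.0264.

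The RNA calls had to be weighed against other groupings of the libraries. Of 35 ways to split the 8 libraries into 4 and 4, 2 gave at least as many calls as the 215 of the genotypes, namely the genotypes themselves and replicates 1 and 2 against 3 and 4, with 5906. That share is too high for chance alone to be excluded by this count, and the larger split follows a structure of the samples. Among the 8 splits that part all 4 pairs of replicates, the highest other count was 1. Within replicates 1 and 2 alone the genotypes differed in 380 genes, and within replicates 3 and 4 alone in 205. Other splits of the same 4 libraries gave at most 10 and 7. The genotype difference was thus seen in each part of the replicates. A batch along that line holds 2 libraries of each genotype on either side. It could not by itself give the genotype calls, so these counts do not test it as their source.

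H3K27me3 was higher in wild type at 4671 regions of the X chromosome. The X held 14157 wild-type and 2594 knockout H3K27me3 peaks in the whole lists, but 69 and 73 with a −log10 q of at least 5. The pattern thus lay in peaks below that threshold. Of the autosomal regions that differ, 40.24% (37.38 to 43.15) were higher in wild type. This argues against depth or scaling that acts on all chromosomes alike. An effect on weak signal of the X alone was not tested. Of the 4671 X regions 36 held a DLX region (0.7707%, 0.557 to 1.06), which argues against a loss of DLX binding at the others. Common regions drawn beside them gave 9.66% (8.95 to 10.4), but were matched in width and not in chromosome or strength. A larger share of female nuclei in the wild-type pool could give this pattern, with 6.42 Y peaks per 100000 in the knockout lists (4.96 to 8.32) and 0.493 in the wild-type lists (0.192 to 1.27). With peaks of a −log10 q of at least 5 the rates were 3.49 (1.19 to 10.3) and 3.61 (1.23 to 10.6), from 3 Y peaks in each genotype, which are too few to decide. The make-up of the pools and the genotype itself therefore stay open.

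Around the chromosome 2 span without knockout signal, histone differences of both directions crowded. Of regions higher in wild type, 3.98% (3.44 to 4.60) lay within 20 Mb of it, or 2.96% (2.50 to 3.51) without the crowded stretch. The share of common regions was 1.40% (1.35 to 1.45). Missing DNA could explain the span itself, since knockout peaks of any mark covered at most 2.118% of it. A haplotype carried along with the knockout allele may explain the regions higher in knockout, 3.718% of which (3.21 to 4.29) lay within 20 Mb of the span, against 1.40% (1.35 to 1.45) of common regions. A loss of DLX binding is left open for these, since 7.386% (4.37 to 12.2) held a DLX region, and draws of common regions of the same mark and width, from within 20 Mb and from all autosomes, gave 14.2% (9.66 to 18.8) and 9.66% (6.25 to 14.2). Of the flanking regions higher in wild type 22.48% (16.1 to 30.4) held one within 20 Mb without the crowded stretch, against 11.6% (6.98 to 17.1) and 9.30% (4.65 to 13.9) in such draws, and within 5 Mb, which does not reach that stretch, 33.9% (23.1 to 46.6) did, against 15.2% (6.78 to 22.0) and 10.2% (3.39 to 17.0), so a loss of DLX binding cannot be told apart from the haplotype there.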
